A study of Homo sapiens with 32 samples.

How the data were processed

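Expression was measured on 32 single-colour Illumina bead arrays of PC-3, an established human prostate adenocarcinoma cell line, each array reporting 20589 probes. Per the labels, flasks received vehicle, cyclophosphamide, which the labels call inactive, or 4-hydroperoxycyclophosphamide, which they call active, for 10, 24 or 48 h. Cyclophosphamide is a prodrug oxidised by liver enzymes, and the hydroperoxy derivative breaks down in culture medium to the 4-hydroxy metabolite without that step. The labels' protocol gives 5.5 µM for the compounds, while the series' design text attaches that dose to the active compound, so the dose of the inactive compound is less certain. Each compound was run as its own experiment of 16 arrays with its own vehicle controls. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

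The deposited signal table holds linear intensity values per probe, and per the submitters' processing notes BeadStudio and R 2.12.0 were used. The authors' series table holds log2 values of the same arrays, as its values and their rank agreement with the intensities show (Spearman correlation at least 0.999 on every array). The normalization method is not given in the sources used here. Medians of the authors' log2 values lay between 7.32 and 7.34 in the inactive-compound experiment and between 7.43 and 7.44 in the active-compound experiment, so the experiments appear to have been normalized separately. No detection p-values or background signals were used here, and no limit of detection can be given for a dim probe.

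The intensities were background-corrected with normexp (offset 50), quantile-normalized over the 32 arrays and taken to log2 with limma 3.58.1 in R 4.3.3. Of the probes, 18332 were paired with 1 gene symbol by the platform annotation, none with several, and 2257 were not listed and stayed unnamed. Entrez identifiers of 18315 of these probes were found in a current gene table, which changed 0 symbols. Probes in the upper 60% by mean log2 over all arrays were kept, and the brightest probe stood for each gene, which left 10598 genes. For 2 of the named values another probe of the gene had passed, and 0 of these had the opposite sign.

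One limma model with a mean for each of the 12 groups was fitted to all 32 arrays, and 14 comparisons were taken from it, each adjusted by Benjamini-Hochberg over the genes tested at 5%. This shares 1 estimate of the spread per gene between the experiments. Test runs on simulated arrays showed a limit of that choice. With equal noise in both experiments, 4.87% of the calls were false for the active compound at 48 h and 4.65% for the inactive one, over 20 draws of 10598 genes. With each experiment's own moderated noise, the shared estimate gave 0.131% false calls for the active compound at 48 h and 33.1% for the inactive one. Fits to the 16 arrays of one experiment gave 5.59% and 5.61%. In comparisons with no simulated change, the shared estimate called a mean of 13.8 genes at 10 h and 9.25 at 24 h for the inactive compound, and 0 for the active one. On these simulated arrays, with noise drawn for each array alone, the shared estimate was therefore too strict for the active compound and too lenient for the inactive one. Control and treated arrays of the inactive-compound experiment partly shared their deviations, as given below, which these simulations did not include. How lenient the shared estimate was for the real arrays is therefore not settled. The comparisons were kept as set before the data were examined, and counts from the fit of the experiment's own 16 arrays, an alternative also set then, are given beside them. In the simulations with own moderated noise, the own fit recovered 98.8% of genes changed by 0.58 on the log2 scale for the active compound at 48 h, with 3 arrays in each group, and 21.8% for the inactive one, with 2. With equal noise it recovered 71.7% and 45.3%. For changes of 1.58 it recovered 100% and 99.3% with own moderated noise. The number of arrays, 2 or 3 in a group, limits the precision of every value.

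Before the data were examined, 25 gene lists were fixed, and the 23 with at least 5 measured members were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry. On simulated lists of unchanged genes, camera gave p under 0.05 for 4% of 200 lists in the active compound's 24 h comparison and for 1.5% in the inactive one's. Named genes are, for each compound and time, up to 10 higher and 10 lower genes with the largest change among those called, and up to 5 each way for the other comparisons. Where none was called, the 3 with the smallest p are given. Up to 4 members of a list with the smallest p may be named, and CDKN1A, GDF15, MDM2, THBS1, VEGFA, HMOX1, CCNB1 and MCM2 were to be given for the active compound. MDM2 did not pass the filter on dim probes. Of the list members, 5 were left out because their older symbols belong to more than 1 gene in the gene table, 4 of them histones. Alternatives covered the background correction, the scaling, the authors' values, the filter, the probe rule, array weights, the variance prior, the arrays in the fit, runs of letters in the sample titles as a block, and each array left out in turn. Pairs of a control and a treated array of the same time and title-letter run were checked after seeing the data and before any fit with them. The labels do not say what these letters mean. Deviations from the group means correlated across genes above 0.1 in 8 of 8 pairs of the inactive-compound experiment (r from 0.159 to 0.686). The 2 pairs at 48 h share 1 value (0.432) by construction, since the deviations in a group of 2 arrays mirror each other. As every value was over 0.1, fits with these pairs as a block are given beside its results. Normalized values are relative, so a change shared by all genes cannot be seen.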

Results

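The arrays compared PC-3 cells under 2 related compounds with vehicle-treated cells of the same experiment. The active-compound experiment held 3 control arrays at each time, 2 treated arrays at 10 h, 2 at 24 h and 3 at 48 h. The inactive-compound experiment held 3 control and 3 treated arrays at 10 h and at 24 h, and 2 of each at 48 h. The 75th percentile of the raw intensity ranged from 431 to 656 over the active-compound arrays and from 275 to 416 over the inactive-compound arrays. The residual SD over genes was 0.122 log2 units in the active-compound experiment and 0.220 in the inactive-compound experiment. No pair of arrays held identical values. Adjusted p-values are from limma.

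After 10 h of the active compound, HMOX1, the haem-degrading enzyme induced by oxidative and electrophilic stress, rose 11.8-fold (log2 change 3.56, SE 0.16, adjusted p = 1.27e-15, 2 treated and 3 control arrays). Its level was 10.98 ± 0.34 (SD, n = 2) against 7.42 ± 0.22 (SD, n = 3). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 1.02 (SE 0.15, adjusted p = 0.00111), and TXNRD1, thioredoxin reductase, by 0.73 (SE 0.14, adjusted p = 0.00952). UGDH, ZBTB21 and KIFC2 rose by 0.87, 0.67 and 0.55. Genes of cell division fell. PSRC1, a spindle protein, fell by 1.12 (SE 0.15, adjusted p = 0.000325), and CENPA, the centromeric histone, fell by 0.99 (SE 0.16, adjusted p = 0.00224). KIF20A, HMMR, CCNB2, GPSM2, PLK1, KIF2C, FAM83D and AURKA fell by 0.95, 0.91, 0.88, 0.87, 0.87, 0.82, 0.79 and 0.76.

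Of the 32 measured genes of the G2/M and mitosis list, 8 fell over all genes tested and 22 did so adjusted over the list alone, with a median of -0.51 (camera, adjusted p = 5.97e-40, and 0.000202 with an estimated correlation). CCNB1, cyclin B1, was at -0.76 (adjusted p = 0.0518). Of the 21 NRF2 and glutathione genes, 3 rose over all genes and 5 adjusted over the list alone (camera, adjusted p = 2.55e-12, and 0.000202 with an estimated correlation). NQO1, a quinone reductase of that list, was at 0.43 (adjusted p = 0.0780). The lists of replication genes and of histones passed camera in opposite directions, and neither held with an estimated correlation (adjusted p = 0.858 and 0.461). CDKN1A, GDF15, THBS1, MCM2 and VEGFA did not pass at this time, with log2 changes of -0.26, 0.16, 0.29, 0.33 and 0.02. In all, 24 genes were called at 10 h, 6 higher and 18 lower, and 171 when only the experiment's own arrays were fitted, with all 24 among them. Without active 10 h replicate 1 the count was 2, and without control replicate 1 or 3 it was 14. With median scaling in place of quantile normalization 6 genes were called, 3 of them lower.

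At 24 h IL6, an inflammatory cytokine, rose 8.49-fold (log2 change 3.09, SE 0.59, adjusted p = 0.0122), from 10.05 ± 0.07 (SD, n = 3) to 13.13 ± 0.20 (SD, n = 2). ATF3, a stress-induced transcription factor, rose by 1.83 (SE 0.20, adjusted p = 9.29e-06). IL24, a cytokine of the IL-10 family, rose by 1.78 (SE 0.28, adjusted p = 0.00117), and DDIT4, an inhibitor of mTOR signalling, by 1.61 (SE 0.27, adjusted p = 0.00302). IL1A, DUSP1, PTGS2, BMP2, TSC22D1 and GADD45A rose by 1.14, 1.09, 1.07, 1.05, 0.95 and 0.85. HMOX1 rose by 0.73 (SE 0.16, adjusted p = 0.0465). The gene that fell was H2BC8, a replication-dependent histone, by 0.60 (SE 0.13, adjusted p = 0.0449). The calls of H2BC8 and HMOX1 lay close to the threshold and were lost without any 1 of the 5 arrays, without the filter on dim probes (adjusted p = 0.0565 and 0.0507), with a trended and robust prior (0.0697 and 0.0615) and with title-letter runs or pairs as a block in the fit of all arrays. That of H2BC8 was also lost without background correction (0.0528) and that of HMOX1 with an offset of 16 (0.0823). Both held in the experiment's own fit (0.00135 and 0.00167).

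Of the 23 unfolded protein response and ATF4 genes, 3 rose at 24 h over all genes and 13 adjusted over the list alone (camera, adjusted p = 4.63e-26, and 0.00026 with an estimated correlation). DDIT3, the stress factor CHOP, rose by 0.79 (SE 0.13, adjusted p = 0.00143), and PPP1R15A was at 0.72 (adjusted p = 0.123). Of 20 p53 targets, 2 rose over all genes and 5 adjusted over the list alone (camera, adjusted p = 2.49e-06, and 0.00026 with an estimated correlation). ATF3 and GADD45A of that list also respond to other stresses. CDKN1A, the cell cycle inhibitor p21, was at 1.06 (adjusted p = 0.0838) and GDF15, a stress-induced cytokine, at 1.59 (adjusted p = 0.120). Of 15 histone genes, a list that lacks H2BC8 because its older symbol was not matched, 0 were called over all genes and 5 fell adjusted over the list alone, with a median of -0.40 (camera, adjusted p = 2.23e-12, and 0.00026 with an estimated correlation). With 4 older symbols matched by hand, H2BC8 among them, 1 of 18 measured members fell over all genes and 6 adjusted over the list alone (estimated correlation, adjusted p = 0.000213). H2BC11 and H2BC5 were at -0.76 and -0.71. The NRF2 and immediate early lists were higher, each with adjusted p = 0.00026 at an estimated correlation. The NF-kB and cytokine list had a median of 0.28 with 3 of 21 members called, and its call was lost with an estimated correlation (adjusted p = 0.0518). The G2/M list had a median of -0.18, with adjusted p = 0.0901 at an estimated correlation. In all, 16 genes were called, 15 higher and 1 lower, and 202 in the experiment's own fit, 118 higher and 84 lower. The count was 4 without active 24 h replicate 1, 9 without replicate 2, 10 without control replicate 1 and 8 without control replicate 3.

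At 48 h the response was broader. IL6 rose 5.43-fold (log2 change 2.44, SE 0.53, adjusted p = 0.0106), GDF15 3.73-fold (1.90, SE 0.34, adjusted p = 0.00246) and KRT34, a hair keratin, 3.41-fold (1.77, SE 0.25, adjusted p = 0.000143). S100P, IL24, ATF3, KRTAP2-4, DUSP1, CLDN1 and TFF1 rose by 1.65, 1.54, 1.52, 1.29, 1.19, 1.18 and 1.17. CDKN1A rose by 1.12 (SE 0.22, adjusted p = 0.00459). CBLN1 fell by 1.05 (SE 0.15, adjusted p = 0.000136), and H4C3, a histone H4 gene, fell by 0.83 (SE 0.15, adjusted p = 0.00261). HOXC4, PRKAG2, UNG, TMSB15A, JMJD8, CNTNAP2, RSAD1 and SVBP fell by 0.73, 0.66, 0.65, 0.64, 0.64, 0.64, 0.62 and 0.62. THBS1, an inhibitor of angiogenesis, was at 0.59 (SE 0.34, adjusted p = 0.549), and VEGFA, an angiogenic factor, at 0.08 (SE 0.09, adjusted p = 0.857).

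Of the unfolded protein response and ATF4 genes, 5 rose and 1 fell at 48 h over all genes, and 14 rose adjusted over the list alone (camera, adjusted p = 1.56e-12, and 0.0236 with an estimated correlation). CTH, an enzyme of cysteine synthesis, rose by 0.83 and STC2, a secreted glycoprotein, by 0.63. HSPA5, the chaperone BiP of the endoplasmic reticulum, fell by 0.59 (adjusted p = 0.00706). Of the p53 targets, 4 rose over all genes and 5 adjusted over the list alone (estimated correlation, adjusted p = 0.0116). Of the NF-kB and cytokine genes, 5 rose over all genes, among them IL1A by 0.88, PTGS2 by 0.81 and CXCL5 by 0.62, and 9 adjusted over the list alone, with adjusted p = 0.0757 at an estimated correlation. Vehicle controls of that list fell from 10 to 48 h, with a median of -0.42. Of 19 interferon-response genes, 2 rose, IFI44 by 0.81 and OASL by 0.57, with adjusted p = 0.0909 for the list at an estimated correlation. Histone genes went both ways. H4C8 rose by 0.83 and H2BC21 by 0.77 while H4C3 fell, and the list had adjusted p = 0.1003 at an estimated correlation. The G2/M list had a median of -0.18 (adjusted p = 0.0757 with an estimated correlation). In all, 172 genes were called, 100 higher and 72 lower, and 1041 in the experiment's own fit, 529 higher and 512 lower, with all 172 among them. Leaving out any of the 6 arrays of this comparison brought the count to between 74 and 96. Under median scaling 142 were called and the share that was higher moved from 58.1% to 86.6%.

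**Figure D1:**
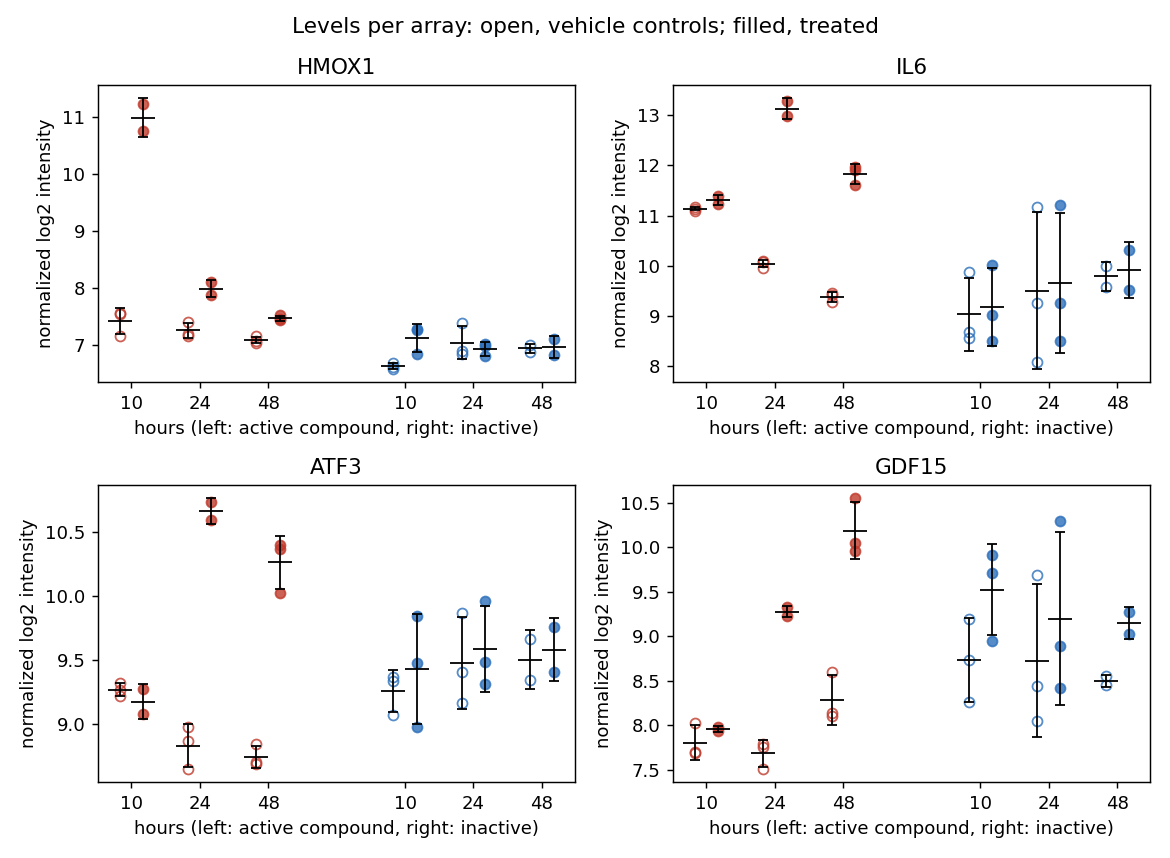
Normalized log2 intensity (vertical axis) of HMOX1, IL6, ATF3 and GDF15 on each array against hours of treatment (horizontal axis), for the active compound on the left of each panel and the inactive compound on the right. Open points are vehicle controls, filled points treated arrays, and black bars the mean ± SD; HMOX1 stood at 10.98 after 10 h of the active compound and at 7.47 after 48 h.

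Genes that rose at 24 h overlapped with those at 48 h. In both, 13 genes rose where 0.142 were expected for independent lists (Fisher's exact test, p = 2.17e-25): AKR1B10, ATF3, BMP2, DDIT3, DUSP1, GADD45A, IL1A, IL24, IL6, PRDM1, PTGS2, RND3 and TSC22D1. These comparisons used different control arrays. Across genes, which are not independent replicates, the log2 changes at 24 and 48 h had r = 0.528, and those at 10 and 48 h r = 0.0674. No gene was called at both 10 h and 48 h, where only 0.0566 shared higher and 0.122 shared lower genes were expected for independent lists. The change of the effect itself from 10 to 48 h was called for 15 genes, 11 higher at 48 h and 4 lower, and for 536 in the experiment's own fit. Without any 1 of 11 arrays this count was between 2 and 9. HMOX1 had an effect lower by 9.08-fold at 48 h (log2 -3.18, SE 0.21, adjusted p = 5.32e-11). CBLN1, CNTNAP2 and ZBTB14 had differences of -1.13, -0.82 and -0.76. S100P, ATF3, KRTAP2-4, FLRT3 and MR1 had differences of 2.00, 1.61, 1.34, 1.18 and 1.07. Averaged over the times, 183 genes were called, 93 higher and 90 lower, and 1160 in the experiment's own fit. Under median scaling the share that was higher moved from 50.8% to 84%. The count was 81, 71 and 107 without active 10 h replicate 1, active 24 h replicate 1 or active 24 h replicate 2. IL6, HMOX1, GDF15, IL24 and ATF3 led the higher genes at 1.90, 1.56, 1.21, 1.14 and 1.08. PSRC1, KIF20A, CENPA, GPSM2 and DLGAP5 led the lower ones at -0.64, -0.61, -0.58, -0.58 and -0.57. Of the G2/M genes, 17 of 32 fell on average (estimated correlation, adjusted p = 0.000728).

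**Figure D2:**
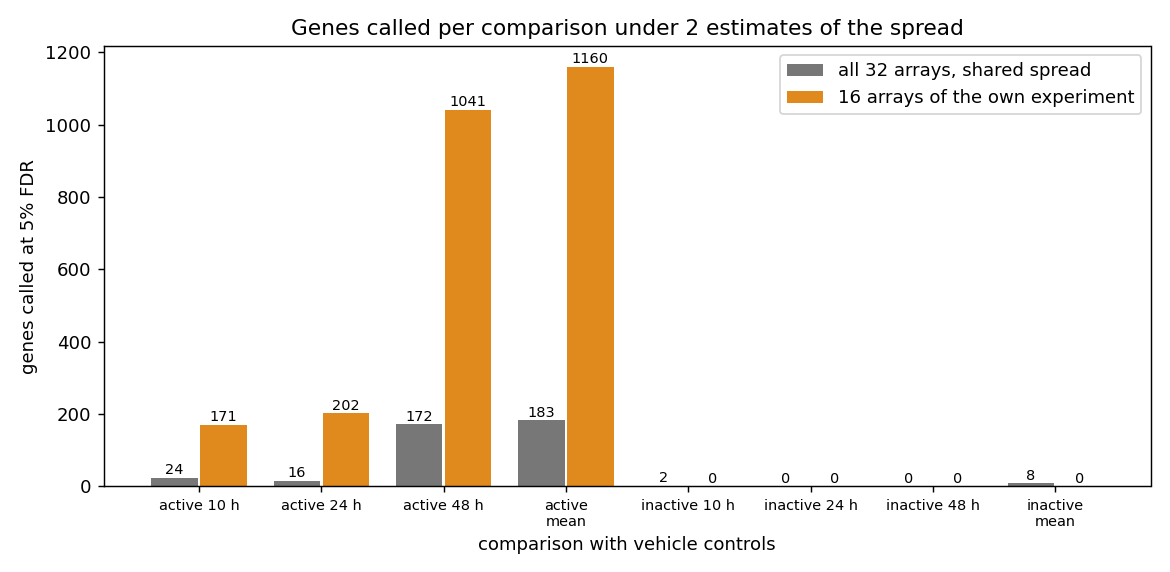
Number of genes called at 5% (vertical axis) in each comparison of treated with vehicle arrays (horizontal axis), from the fit of all 32 arrays with a shared spread (grey) and from the 16 arrays of the compound's own experiment (orange). At 48 h the active compound had 172 and 1041 genes and the inactive compound 0 and 0.

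In its own experiment the inactive compound gave 0 calls when every array counted alone and 9 on average over the times when arrays were paired. At 10 and 24 h, 4 arrays of that experiment, a control and a treated one at each time, lay on the other time's side of the axis between the remaining arrays of those times. In the shared fit, 2 genes were called at 10 h, STC2 higher by 0.52 (SE 0.10, adjusted p = 0.0435) and HEATR3 lower with a log2 change of -0.75 (SE 0.12, adjusted p = 0.0139). At 24 and 48 h limma called 0 genes in the shared fit, with 321 and 421 at an unadjusted p under 0.05. At 24 h the smallest p belonged to AKAP10, GSAP and TRIM25 (0.54, 0.51 and 0.48), and at 48 h to IL7R, EPC1 and HMGA1 (-0.93, -0.66 and -0.56). On average over the times, 8 genes were called. ID1, an inhibitor of differentiation factors, MT2A, a metallothionein, ZBTB14, STC2 and PNPLA6 had changes of 0.48, 0.38, 0.35, 0.35 and 0.34, and IL7R, CLTRN and SYNCRIP of -0.52, -0.33 and -0.32. The fit of the experiment's own 16 arrays called 0 genes at 10, 24 and 48 h and on average, with 525, 112, 157 and 451 genes at an unadjusted p under 0.05. In simulations with this experiment's own spread, the shared fit called a mean of 13.8 genes at 10 h where nothing had been changed. Without the 4 arrays on the other time's side, the shared fit called 44 genes on average. In the shared fit the count at 10 h was 169, 30 and 0 without treated replicate 1, 2 or 3, and 5, 1 and 0 without control replicate 1, 2 or 3. The count on average was 32, 32, 30, 16, 15 and 1 without treated 10 h replicate 1 or 3, control 24 h replicate 3, control 10 h replicate 2, treated 24 h replicate 1 or control 48 h replicate 1. At 48 h it was 1 without treated replicate 2.

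These fits count differences between the runs as noise, although control and treated arrays of the same time and title-letter run deviated together from their group means. With the 8 pairs as a block, an alternative chosen after seeing the data, the experiment's own fit called 0 genes at 10, 24 and 48 h, with 1271, 401 and 454 at an unadjusted p under 0.05, and 9 on average, 6 higher and 3 lower. ASNS, asparagine synthetase, rose by 0.71 (SE 0.09, adjusted p = 0.00944), GDF15 by 0.64 (SE 0.08, adjusted p = 0.00944) and DDIT4 by 0.61 (SE 0.07, adjusted p = 0.00944). RDH10, ID1 and TRIB3 rose by 0.53, 0.48 and 0.42, and IL7R, CXCL6 and PNPT1 fell by 0.52, 0.48 and 0.43. Each of the 9 had the same sign in 8 of 8 pairs, but they were chosen on these same pairs, so this is no separate support. Without either 48 h pair 0 genes were called. With the 24 h pairs left out in turn the counts were 4, 5 and 5, all among the 9, and with the 10 h pairs left out 7, 7 and 12, with 6, 7 and 8 among the 9. Median scaling called 7 genes, 5 of them among the 9, and the authors' values 38, all 9 among them. Of the 8 genes of the shared fit, 2 were among the 9.

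Of the gene lists, the unfolded protein response and ATF4 list stood out under the inactive compound. All 23 members had a positive mean change over the times, with a median of 0.23 (camera, adjusted p = 7.47e-14, and 0.0308 with an estimated correlation). Of them 1 was called over all genes and 12 adjusted over the list alone, both in the shared fit. ASNS, asparagine synthetase, DDIT4 and DNAJB9 were at 0.71, 0.61 and 0.38. In the experiment's own fit the list kept its call (camera, adjusted p = 5.42e-13), and over the listed alternatives, each taken alone, the adjusted p ranged from 3.51e-16 to 0.0308. With pairs as a block 3 of its members were called (camera, adjusted p = 1.06e-15), and its call was lost with an estimated correlation (adjusted p = 0.0729). Camera then also called p53 targets (0.0423), NRF2 genes (0.0445), ribosome biogenesis (0.0423) and metallothioneins (0.0423) at 24 h, immediate early genes and metallothioneins at 48 h (both 0.0319), and NRF2 and immediate early genes on average (0.0456 and 0.00938). With pairs no list held for the inactive compound at an estimated correlation. At single times its call did not hold with an estimated correlation (adjusted p = 0.403, 0.0925 and 0.381 at 10, 24 and 48 h). The G1/S and replication list had a median of -0.18 with 0 of 30 members positive, and its call was lost with an estimated correlation (adjusted p = 0.267), as was that of the heat shock list (0.267).

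**Figure D3:**
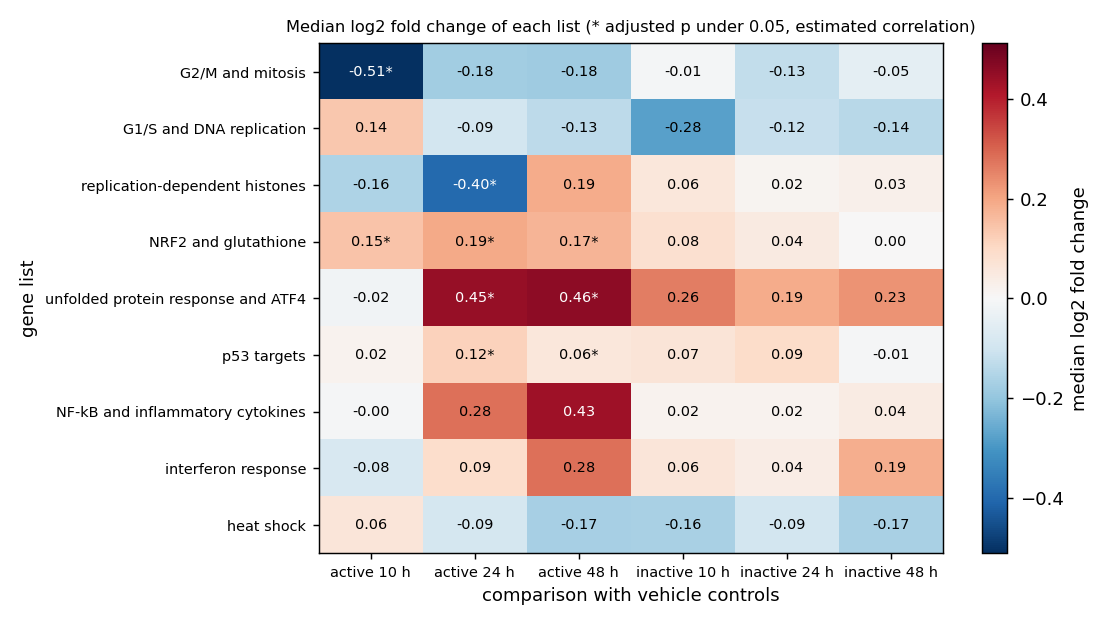
Median log2 fold change (colour and printed value) of the measured members of 9 gene lists (vertical axis) in each comparison with vehicle controls (horizontal axis). Asterisks mark an adjusted p under 0.05 with camera at an estimated correlation, and the G2/M list at 10 h of the active compound has the lowest median, -0.51.

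The active compound carries a hydroperoxy group on the oxazaphosphorine ring that cyclophosphamide lacks, and the effects of both were compared at times matched by label. The 10 and 24 h labels of the inactive-compound experiment are in doubt, so the match at these times is uncertain. Each compound had its own experiment, so a difference between compounds is also one between experiments. At 10 h HMOX1 differed by 3.06 (95% interval 2.63 to 3.50, adjusted p = 1.39e-10), with a change of 0.50 under the inactive compound that did not pass (adjusted p = 0.197). At 24 h ATF3, IL1A and BMP2 differed by 1.72, 1.15 and 0.96 (adjusted p = 0.00824, 0.0430 and 0.0347). At 48 h RGS4 and FLRT3 differed by 1.16 and 1.17 (adjusted p = 0.00237 and 0.00376). On average 21 genes differed, 15 with a higher effect of the active compound, led by HMOX1, KRT34, IL24, ATF3 and DUSP1 at 1.42, 1.08, 1.001, 0.96 and 0.83. SOX21, ID1, GPSM2, MT2A and CCDC167 had differences of -0.82, -0.68, -0.61, -0.52 and -0.52. With an own spread for each experiment, 2, 4, 2 and 18 genes differed at 10, 24 and 48 h and on average, and all 18 were among the 21. With pairs as a block in the inactive-compound experiment as well, 63, 35, 75 and 240 genes differed, and all 21 were among the 240. Without the 4 arrays on the other time's side of that axis, the shared fit gave 18 at 10 h and 82 on average. Under median scaling 17 genes differed on average, 100% of them with a higher effect of the active compound against 71.4%. Leaving out single arrays gave 1 to 11, 0 to 5, 1 to 5 and 11 to 49 genes. The highest counts came without inactive 10 h replicate 3, inactive 24 h replicate 1, inactive control 48 h replicate 2 and inactive control 24 h replicate 3. At 24 h 0 genes differed without active 24 h replicate 1 or inactive 24 h replicate 3. For IL6 the difference at 24 h was 2.93, with an interval of 1.498 to 4.37 on the own spreads, and did not pass over all genes (adjusted p = 0.309). For GDF15 the average difference was 0.58, with an interval from -0.000863 to 1.15 on the own spreads. STC2 had an average difference of -0.06 (own-spread interval -0.24 to 0.13), and VEGFA of -0.01 (-0.17 to 0.16 in the shared fit). With an estimated correlation, 2, 4, 0 and 3 of the 23 lists differed at 10, 24 and 48 h and on average. At 10 h the G2/M list had a lower effect of the active compound and the NRF2 list a higher one (adjusted p = 0.0111 and 0.0186). At 24 h histones had a lower effect (0.00783), and p53 targets, NRF2 and immediate early genes a higher one (0.0198, 0.0206 and 0.0442). On average the G2/M list was lower (0.0291), and p53 targets and NRF2 genes were higher (0.0291 and 0.00472). The unfolded protein response list was called by camera at 10, 24 and 48 h, without holding at an estimated correlation (0.377, 0.0979 and 0.512), and was not called on average. At 10 h its 4 members with the smallest p, STC2, ASNS, PSAT1 and DDIT4, had a lower effect of the active compound (-0.56, -1.18, -0.56 and -0.69). At 24 and 48 h its median was higher under the active compound (0.45 and 0.46) than under the inactive one (0.19 and 0.23).

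Vehicle controls at 48 h against 10 h, averaged over the experiments, gave 0 genes in limma, with 364 at an unadjusted p under 0.05. The controls of the active-compound experiment alone gave 1226 genes and those of the inactive-compound experiment 0, with 240 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the changes of the experiments had r = -0.476, and 1066 of the 1226 had the opposite sign in the other experiment. The 10 h labels of the inactive-compound experiment are in doubt, and these values rest on them. With 10 and 24 h labels exchanged in its first runs r was 0.0433, and with those of the third run exchanged -0.556. DBP, GPR37 and GAL3ST2 had the smallest p, at 0.37, 0.32 and -0.36. Of the lists not yet named, those of crosslink repair, cholesterol synthesis, hypoxia and glycolysis, cyclophosphamide metabolism, matrix genes, ribosomal proteins and oxidative phosphorylation were called by camera in none of the 14 comparisons, though cholesterol synthesis, matrix genes and oxidative phosphorylation were in the controls of the active-compound experiment alone (estimated correlation, adjusted p = 0.00459, 0.0628 and 0.135), and cholesterol synthesis, in the other direction, in those of the inactive-compound experiment (0.770). Angiogenesis regulators were called at 48 h of the active and 24 h of the inactive compound (estimated correlation, adjusted p = 0.0757 and 0.0925). Epithelial genes were called at 48 h of the active compound and in the difference there (0.176 and 0.443). Ribosome biogenesis was called higher at 24 h of the active compound, lower for the inactive average and higher in the differences at 24 h and on average (0.449, 0.360, 0.260 and 0.315). Metallothioneins were called for the inactive average and lower in the difference at 24 h (0.126 and 0.0999), and apoptosis regulators for the controls (0.114). The interferon and heat shock lists were called in several of the 14 comparisons and held with an estimated correlation in none, while heat shock held in the controls of the active-compound experiment alone (0.0424). Of the other lists fixed for mixed cells, the androgen-responsive list was not called in any comparison, and the fibroblast and endothelial list and the leukocyte list had too few measured members for a test, with no member called.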

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

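The test of exchanged labels was chosen after the arrangement of the arrays had been seen, and the reading of the test of a run difference was changed after its value had been seen. The fits with pairs of time and run, and the tests on them, were added after seeing the data, as were the ratio with genes chosen and measured on different arrays and the covariance of effects from separate pairs. The reading of the noise test was changed after its own value had been seen, and that of the range test after that covariance had been seen. The test of the difference between the compounds passed for HMOX1 at 10 h (3.06), for ATF3 (1.72), IL1A (1.15) and BMP2 (0.96) at 24 h, and for FLRT3 (1.17) and RGS4 (1.16) at 48 h. On average over the times it passed for HMOX1 (1.42), KRT34 (1.08), IL24 (1.001), ATF3 (0.96), DUSP1 (0.83), SOX21 (-0.82), ID1 (-0.68), GPSM2 (-0.61), MT2A (-0.52) and CCDC167 (-0.52). The effect of the active compound differed between 48 and 10 h for S100P (2.00), ATF3 (1.61), KRTAP2-4 (1.34), FLRT3 (1.18), MR1 (1.07), HMOX1 (-3.18), CBLN1 (-1.13), CNTNAP2 (-0.82) and ZBTB14 (-0.76). All are log2 differences from the shared fit.

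Other splits of the same arrays were drawn. For the active average, 1 of 100 splits called as many genes as the real 183, the highest other being 5. For the average difference it was 1 of 100, with a real count of 21 and a highest other of 13. A chance split of these arrays can thus be excluded for both. A chance difference between cultures cannot, since the arrays of a group may be technical replicates. For the inactive average 17 of 100 splits called at least the real 8 genes and the highest called 1212, so chance cannot be excluded for that fit. With the pairs of time and run as a block in the experiment's own fit, 1 of 100 exchanges of treated and control within pairs called as many as the real 9, the highest other being 1. That share is under 0.05, but the pairs were chosen after seeing the data, which the exchanges do not allow for. Without either 48 h pair 0 genes were called. Chance is therefore not excluded for the fit with pairs. At 10 and 24 h that fit had 0 against a highest other of 0, in 4 of 4 exchanges, too few for a share under 0.05. For the controls at 48 h against 10 h all 100 splits gave at least the real 0, with a highest of 87. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The active compound at 48 h had 172 against a highest other of 0 (1 split as high), the inactive compound at 10 h 2 against 922 (5 splits as high) and at 24 h 0 against 407 (10 splits as high). Splits that call many times the real count point to a structure of the arrays of the inactive-compound experiment. In the split with 922, control and treated replicate 3 lay on the same side.

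More genes were called for the active compound, 183 against 8 on average in the shared fit and 1160 against 0 in the own fits without pairs. The size of the gap depends on the fit. With pairs as a block it was 1169 against 9 in the own fits and 426 against 181 in the fit of all arrays. In the simulations without pairs the shared spread of all arrays was too lenient for the inactive compound. With an own spread for each experiment the effects of the compounds differed for 18 genes, and for 240 with pairs as a block in the inactive-compound experiment. Simulated noise added to the active-compound arrays up to the other experiment's spread left a median of 135 called genes over 20 draws, with a lowest of 107. That noise was drawn for each array alone, while the spread of the other experiment is partly shared within pairs. This test alone therefore does not exclude the larger spread. The size of the effects was therefore taken from the covariance across genes of average effects from separate pairs, to which the noise of single pairs adds nothing on average. Its median was 0.0113 for the active compound (0.0109 to 0.0115 over 12 splits of the pairs) and 0.00488 for the inactive one (0.00326 to 0.00559 over 18 splits), a ratio of 0.432. The inactive values lay below the active ones in every split, but the highest was not below the bound set for excluding the larger spread, 0.00544. With effects limited to 0.5 either way it was not either (0.00552 against 0.00478). Together with the noise draws and the own fits with pairs (1169 against 9), these values argue against the larger spread as the only cause of the gap. A part of it in the gap is left open. A narrower signal range would scale effects by the ratio of the ranges, 0.737, and their covariance by its square, 0.543. Over the 183 genes the inactive compound's median effect was 0.158 of the active one's (bootstrap 95% interval over genes 0.126 to 0.229). With 183 genes chosen on part of the active-compound arrays and measured on the others, the ratio was 0.196 (0.142 to 0.253) and 0.187 (0.128 to 0.251). These intervals measure scatter over genes, which are not independent replicates, and leave out the spread between arrays. They lie under 0.368, the bound first set, and argue against the same effects on a narrower scale at these genes on these arrays. That bound took the compounds to act on the same genes. Over all genes the ratio of 0.432 is closer to the square, 0.543, but such scaling of normalized effects is itself untested. The values therefore do not decide whether the range bears on the count. Left open are the larger spread as the whole or a part of the cause, a narrower range, fewer arrays at 48 h and a difference in action of the compounds. So is any difference between the experiments in cells or handling. These cannot be told apart as causes of the gap, since the design confounds them with the compound.

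The letters that end the sample titles divide the inactive-compound experiment into 3 runs, whose meaning the labels do not give. Arrays of the third run labelled 24 h lay with arrays of the other time, while those labelled 10 h lay only slightly past the middle towards it. On the axis from 10 h (0) to 24 h (1) of the other runs, 4 of 4 such arrays lay on the other label's side of 0.5, those labelled 10 h at 0.5803 and 0.551 and those labelled 24 h at 0.0895 and -0.00836, while 8 of 8 other arrays lay on their own side. Labels exchanged in that run may account for this, but the active-compound experiment points the other way. Across genes, its change from 10 to 24 h had r = -0.441 with that of the first runs and r = 0.352 with that of the third. By that reference an exchange would lie in the first runs and not in the third. The changes of the controls from 10 to 48 h had r = -0.476 between the experiments as labelled. That r was 0.0433 with labels of the first runs exchanged and -0.556 with those of the third. A run difference unrelated to time was to be favoured by any correlation under 0.1, so -0.441 met that bound as first set. The bound had not foreseen opposed changes, which are not unrelated ones, and after the value was seen the test was read as deciding nothing. Exchanged labels and a run difference therefore cannot be told apart. No array was relabelled.

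Genes of the unfolded protein response and ATF4 list were higher under the inactive compound, with a median of 0.23 over 23 genes. Of 100 within-time splits, 2 gave a median as far from 0, the real one included, and the other reached 0.241. Of 100 exchanges within pairs, 1 did so, the real one with 0.228, and the highest other reached 0.214. With each of the 16 arrays left out the median stayed at 0.181 or above, so 1 array does not account for it. For this list taken alone both shares were under 0.05, but 1 other within-time split gave a larger median, so chance is not excluded. The list was also picked as the one of 23 that held its call, which neither set of splits allows for. With pairs as a block its call in camera was lost at an estimated correlation (adjusted p = 0.0729). A response to the compound is a candidate explanation, and a difference in medium or handling between treated and control flasks was not tested.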

How the results depend on the processing

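The alternatives without 4 arrays, with controls of 1 experiment alone, with an own spread for each experiment, with pairs of time and run and with list members matched by hand were chosen after seeing the data. With only the experiment's own arrays, the active compound had 171, 202, 1041 and 1160 genes at 10, 24 and 48 h and on average, and 536 for 48 h minus 10 h, with every gene of the shared fit among them. The inactive compound then had 0 at 10 h and 0 on average, where the shared fit had 2 and 8. On simulated arrays with unequal spread the shared estimate gave 33.1% false calls for the inactive compound at 48 h and 0.131% for the active one, but the own fit also recovered fewer of the inactive compound's changes of 0.58, 21.8% against 57.4%. Whether the 2 and 8 calls were false was not settled, and with pairs as a block 2 of the 8, ID1 and IL7R, were called again in the own fit, and both of the 2 and all 8 in the fit of all arrays. For the active compound the simulated calls at 48 h rose from 191 to 211, which does not show the cause of the rise from 172 to 1041, and that cause was not tested. With only the groups compared there were 49, 127 and 989 genes for the active compound and 0 for the inactive compound at 10 h. Array weights gave 76, 259, 1335 and 1082 genes for the active compound at 10, 24 and 48 h and on average and 374 for 48 h minus 10 h, 0 and 5 for the inactive compound at 10 h and on average, and 6, 5, 12 and 65 for the differences. The authors' values gave 56, 55, 561 and 573 for the active compound, 153 for 48 h minus 10 h, and 10, 9, 30 and 57 for the differences. For these and the following values the cause was not tested. Median scaling gave 6 genes for the active compound at 10 h, 24 for 48 h minus 10 h, 0 and 0 for the inactive compound at 10 h and on average, and 11 for the difference at 48 h. It raised the share of higher calls from 25% to 50% at 10 h, from 58.1% to 86.6% at 48 h and from 50.8% to 84% on average for the active compound, from 73.3% to 91.7% for 48 h minus 10 h, and from 71.4% to 100% for the average difference. The authors' values moved that share from 93.8% to 78.2% for the active compound at 24 h, and from 100% to 30% and 80% for the differences at 10 and 48 h. For the inactive compound they moved it from 50% to 100% at 10 h and from 62.5% to 83.3% on average. Without background correction there were 4 genes for the inactive compound at 10 h and 2 and 4 for the differences at 10 and 48 h, with shares of 75%, 100% and 75% higher, and 75% for the inactive average and 60% for the average difference. With an offset of 16 there were 18 for the inactive average, 1 for the difference at 24 h and 9 for 48 h minus 10 h, and shares of 33.3% for the inactive compound at 10 h and 57.1% for the average difference. The stricter filter gave 6 and 14 for the inactive compound at 10 h and on average and 2 and 1 for the differences at 10 and 24 h, no filter gave 1 and all probes 12 for the inactive compound at 10 h. A trended and robust prior gave 5 for the inactive compound at 10 h and 3 and 5 for the differences at 10 and 48 h. Title-letter runs as a block gave 1, 1 and 13 for the inactive compound at 10 h, at 48 h and on average and 11 for the difference at 48 h. Without the 4 arrays that stand apart, in the shared fit, there were 5 and 44 for the inactive compound at 10 h and on average and 18, 1 and 82 for the differences at 10 h, 24 h and on average. Controls of the active-compound experiment alone gave 1226 genes at 48 h against 10 h, and an own spread gave 2 for the difference at 10 h. Camera made 93 list calls, of which 26 held with an estimated correlation, and fry made 39. Leaving out each array gave 2 to 32, 4 to 11, 74 to 96 and 71 to 152 genes for the active compound at 10, 24 and 48 h and on average, and 2 to 9 for 48 h minus 10 h. For the inactive compound it gave 0 to 169, 0 to 0, 0 to 1 and 1 to 32, for the differences 1 to 11, 0 to 5, 1 to 5 and 11 to 49, and for the controls 0 to 0. Over 159 values of named genes, 3213 of 3714 recomputed values kept direction and side of the threshold, 372 lost the call, 122 gained one and 7 changed sign. The sign changes were MCM2 in the active average (0.0072 with median scaling) and VEGFA, not called, at 10 h (-0.0267 to 0.0914 over single arrays left out, below 0 without control replicate 1 or 2 or treated replicate 2) and in 48 h minus 10 h (-0.0146 to 0.103, below 0 without 10 h control replicate 3, and -0.0146 in both fits with pairs). Of the called lists, 2010 of 2268 values kept both, 254 lost the call and 4 medians changed sign: immediate early genes in the average difference (-0.0384, stricter filter), replication (-0.238 to 0.0829) and heat shock genes (-0.249 to 0.00576) for the inactive compound at 24 h, above 0 without treated replicate 3, and NRF2 genes in 48 h minus 10 h (-0.104 to 0.00755, above 0 without 10 h control replicate 1). The labels give no replicate numbers, so pairs were read from time and title-letter run. As a replicate block in the fit of all arrays they gave 33, 53, 587 and 426 genes for the active compound, 97 for 48 h minus 10 h, 69, 0, 1 and 181 for the inactive compound and 18, 24, 93 and 120 for the differences. In the fits of the own experiment they gave 83, 178, 1320, 1169 and 489 for the active compound and 0, 0, 0 and 9 for the inactive compound. With an own spread and the block in the inactive-compound experiment, the differences had 63, 35, 75 and 240 genes. In the active-compound experiment deviations correlated above 0.1 in 6 of 7 pairs (r from -0.0448 to 0.248), and 6 of 7 treated arrays correlated best with the control of their own run, a hint from the data and not the design. With the block in the fit of all arrays 19 of the 24 calls at 10 h and 13 of the 16 at 24 h were kept. Among those lost were KIFC2 at 10 h and H2BC8 and HMOX1 at 24 h. List tests of the differences were not made with own spreads and the block. The control comparison cannot be fitted with this block. With 5 list members matched by hand camera again made 93 calls. Slide as a block was not run, since the columns name no slides. Where a group was left with 1 array, that array is assumed to vary like the other groups. The lower raw signal of the inactive-compound experiment, with no detection values used, leaves unknown how many of its dim probes lay at background.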

Other observations

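The fits of 1 experiment's controls alone, the test of their difference and the levels against the 10 h controls were chosen after seeing the data. In the vehicle controls of the active-compound experiment, fitted alone, 1226 genes differed between 48 and 10 h (limma, 632 higher and 594 lower), while those of the inactive-compound experiment gave 0, with 240 at an unadjusted p under 0.05. The change differed between the experiments for 58 genes, on own spreads, and had r = -0.476 across genes, which are not independent replicates. These values rest on 10 h labels of the inactive-compound experiment that are in doubt. With its 10 h controls taken 1 at a time r was -0.431, -0.340 and -0.275, and it was 0.0433 with 10 and 24 h labels exchanged in the first runs and -0.556 with those of the third run exchanged. LXN, INSIG1, an inhibitor of sterol synthesis, SCNN1A, HAS3 and RDH10 were higher at 48 h by 1.503, 1.37, 1.21, 1.19 and 1.15. IL6, TFF1, SCG5, CXCL8, a neutrophil chemokine, and TAGLN had changes of -1.75, -1.56, -1.40, -1.37 and -1.32. Of 18 cholesterol synthesis genes 12 rose, with a median of 0.49 (camera, adjusted p = 3.31e-14, and 0.00459 with an estimated correlation). In the controls of the inactive-compound experiment that list had a median of -0.36 with 2 of 18 positive (camera, adjusted p = 6.36e-06, and 0.770 with an estimated correlation). Of 21 NF-kB and cytokine genes 12 fell, with a median of -0.42 (camera, adjusted p = 1.10e-15, and 0.00459 with an estimated correlation). In the other experiment's controls its median was 0.12 (camera, adjusted p = 0.666).

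The rise of IL6 under the active compound at 24 and 48 h is thus measured against a control level that fell. IL6 controls of that experiment stood at 11.13, 10.05 and 9.39 at 10, 24 and 48 h, and treated arrays at 11.31, 13.13 and 11.83. Both treated levels of IL6 at the later times lay above the 10 h controls. Of the 100 genes called higher at 48 h, the controls of 32 fell from 10 to 48 h and those of 9 rose. Over all 10598 genes 594 fell and 632 rose. The same 48 h controls enter both comparisons, which by itself favours falls among genes called higher, so the excess is partly built in. For 28 of the 32 the mean treated level at 48 h lay above that of the 10 h controls, a difference that was not tested. For 4 it lay below: TFF1 (8.54 against 8.93), CCL20 (7.98 against 8.15), CXCL5 (7.63 against 7.74) and IL4I1 (7.11 against 7.34). CXCL8, not called at 48 h (adjusted p = 0.106), had a treated level of 13.27 against 13.46.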
